A study of Mus musculus with 24 samples.

How the data were processed

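RNA from mouse extraocular muscle, the muscles that move the eye, was measured on 24 Affymetrix arrays with 1 colour. Per the labels, the arrays fall into 8 groups of 3: wild type (called control in the labels) and mdx mice at 14, 28, 56 and 112 days. Group and replicate number were taken from the sample titles. These titles name no strain, so an effect of the mdx mutation cannot be told apart from a difference of strain, where there was one. Nothing in the labels says that the arrays came from separate animals, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

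The deposited values are intensities on a linear scale, 1 per probe set and array, made by the authors from the scanned arrays. The labels name only a standard Affymetrix procedure; the scanner software, its version and its settings are not given in the sources used here. On every array the mean without the lowest and highest 2% of the deposited intensities lay between 1500.5 and 1500.9, so that each array had been brought to 1 common level before deposit. No detection calls were used here. The table held 12488 probe sets with 0 missing values, and 0 columns were left unused.

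The following choices were made before the data were examined. Values under 1 were set to 1, which applied to 44 values. Each array was scaled by 1 factor to a mean of 500 without the lowest and highest 2% of values, 16 was added and the log2 taken. The offset of 16 equals 48.0 on the deposited scale. Intensities are given on the scale with a mean of 500. Fold changes are on the log2(value + 16) scale, which understates the change of dim probe sets. The 66 control probe sets of the manufacturer were removed, which left 12422. Probe sets with a mean log2 level at or above the 40th percentile, an intensity of 125.7, were tested, which left 7453.

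Probe sets were named through the platform annotation, which gave 1 gene symbol for 10833 probe sets, several for 396 and none for 1193. Of those with 1 symbol, 10817 were matched to a RefSeq gene table of the GRCm38.p6 assembly, and 0 symbols changed. That table was used for names only and no coordinates are given. Among the tested probe sets 6714 had 1 symbol, for 5675 genes. A probe set with several symbols was counted and never named by a gene.

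One limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 8 groups was fitted to all 24 arrays, with 16 residual degrees of freedom and a variance trend on intensity (lmFit and eBayes). All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each contrast, and a probe set was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from this model, and errors of group means are standard deviations (SD). The contrasts were mdx against control at each age and averaged over the 4 ages, the genotype by age interaction (an F test), the control ages together (an F test), 112 against 14 days in each genotype, and the steps between neighbouring ages in control muscle. The difference of the 112 against 14 day change between genotypes was tested as a contrast of its own.

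Named genes followed a fixed rule. Dmd was given in every group. For mdx against control the rule took up to 10 rising and 10 falling genes past the threshold, with 1 symbol and 1 probe set per gene, whose mdx arrays all lay on 1 side of the control arrays (for the average over ages, whose difference had the same sign at every age). For 112 against 14 days in control muscle the same rule applied. The interaction took the 10 smallest p-values past the threshold. From a gene list, up to 4 members with the smallest p were named, together with Utrn and the myosin genes its description needs. Myh13, the myosin heavy chain typical of extraocular muscle, had no probe set under that symbol in the annotation and was not analysed here.

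The 26 gene lists covered the dystrophin complex, myogenic regeneration, muscle isoforms, calcium handling, energy metabolism, stress responses, the junction between nerve and muscle, protein breakdown, proliferation, the extracellular matrix, inflammatory cells and markers of tissues next to the eye muscles. A list with at least 5 measured genes was tested with camera at a preset correlation between genes of 0.01, and beside it with an estimated correlation and with fry. P-values were adjusted over the 25 lists tested. The probe set with the highest mean stood for a gene, so a gene can have another value in its list than as a named gene. The sex-linked list had 2 measured genes and was not tested. For the average over ages, the list means were also tested by an exact permutation of the genotype labels within each age, over all 160000 arrangements.

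The arrays were compared before any averaging, and 0 columns were identical. A pairing of arrays by replicate number was checked by correlating the deviations of mdx and control arrays of the same age and number from their group means. At 28 days the 3 correlations were 0.322, 0.199 and 0.127, all over the limit of 0.1 set for pairing, so that the numbers were taken to pair the 28-day arrays. This pairing comes from the data, since the labels do not say that a number marks a litter or a day. It was not tested against chance, and 3 arrays a side allow few matchings, so it stays an assumption. At the other ages at least 1 pair lay under the limit. At 112 days the correlations of the same number, 0.0667, 0.0904 and 0.107, still exceeded those of different numbers, the highest being -0.0161. A weaker pairing there stays open. The model above held no term for replicate number.

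The tests were checked on simulated data made from the mean level and residual spread of each of the 7453 tested probe sets. In each simulation 200 probe sets were changed by a fold of 1.5, 2 or 4, with noise independent between probe sets. For the genotype comparisons this gave more calls than the real data, 102 against 4 at 56 days. The adjusted threshold is then stricter in the real data, so the shares for these comparisons overstate what could be recovered there. For the average over ages, 86.6% of genes changed by a fold of 2 and 46.3% of genes changed by a fold of 1.5 were recovered. For mdx against control at 56 days these shares were 46.3% and 8.96%. For 112 against 14 days in control muscle they were 38.8% and 10.4%, and for the difference of that change between genotypes 22.4% and 1.49%. In control muscle the simulation gave 99 calls, against 813 in the real data. The adjusted threshold is then looser in the real data, so the shares for control muscle understate what could be recovered there. For the interaction they were 13.4% and 0%.

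Alternatives covered the scaling of the arrays, the offset, the filter on dim probe sets, the variance trend, array weights, a block by replicate number, smaller sets of arrays in the fit and leaving out each array in turn. After the data had been seen, fits without the 2 arrays that stood apart from the others and with the largest signal of each array as a covariate were added, as were the alternatives for the steps between ages and for the difference between genotypes, the gene list tests with each array left out, and the values of Myh3 and Myh8 without control 112-day replicate 1. Counts were compared with those of other splits of the arrays, all 10 splits for a single age and 100 drawn with a fixed seed elsewhere. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.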

Results

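Extraocular muscle was compared between wild type and mdx mice. The mdx mouse carries a premature stop codon in Dmd, the gene for dystrophin, and is a model of Duchenne muscular dystrophy, a disease that largely spares the eye muscles. Total RNA of each genotype was measured at 14, 28, 56 and 112 days, with 3 arrays in each of 8 groups. The median deposited intensity of an array lay between 535.3 and 806.3 and its largest intensity between 26246 and 85681. The log2 levels of pairs of arrays correlated with r between 0.754 and 0.964 across probe sets, which are not independent replicates. A pair of arrays stood apart: control 56-day replicate 2 had a mean correlation with the other arrays of 0.806 and control 112-day replicate 1 of 0.833, against 0.866 for the lowest of the rest and a median of 0.904.

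Dmd RNA was lower in mdx muscle at every age. Its intensity in control muscle was 305.2 ± 47.6 at 14 days, 218.0 ± 18.3 at 28 days, 547.3 ± 181 at 56 days and 349.1 ± 106 at 112 days (SD, n = 3 arrays each). In mdx muscle it was 134.2 ± 45.0, 115.3 ± 18.0, 128.0 ± 20.8 and 117.7 ± 10 at the same ages. At all 4 ages every mdx array lay below every control array, an order that chance gives in either direction at 10% for 1 age. Averaged over ages, the log2 fold change was -1.33 ± 0.14 (SE, adjusted p = 9.72e-06), a fold of 2.51. By age, the log2 fold change was -1.13 (adjusted p = 0.691) at 14 days, -0.84 (adjusted p = 1) at 28 days, -1.92 (adjusted p = 0.00323) at 56 days and -1.41 (adjusted p = 0.118) at 112 days, each ± 0.28. Without control 112-day replicate 1 the change at 112 days was -1.66 and passed the test (adjusted p = 0.0424). The position of the probe set relative to the mutation was not analysed here.

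Averaged over the 4 ages, mdx muscle held more RNA of Myl4, the embryonic and atrial alkali light chain of myosin, of Ctss, the lysosomal protease cathepsin S, and of the metallothionein gene Mt2. Myl4 rose by a log2 fold change of 1.10 ± 0.12 (SE, adjusted p = 9.72e-06), a fold of 2.15, and was above the control mean in 12 of 12 mdx arrays. Mt2 rose by 0.93 ± 0.17 (adjusted p = 0.0224), above the control mean of its age in 12 arrays, and Ctss by 0.69 ± 0.12 (adjusted p = 0.0119), above it in 11. Besides Dmd, Erdr1 fell, with a log2 fold change of -1.41 ± 0.18 (adjusted p = 0.000134) and a lower level in 12 of 12 mdx arrays. Qrsl1, an amidotransferase gene, fell with a log2 fold change of -0.47 ± 0.09 (adjusted p = 0.0449), and 11 of its 12 mdx arrays lay below the control mean. A second Myl4 probe set had a log2 fold change of -0.02 ± 0.13 (adjusted p = 0.982), and a second Erdr1 probe set had -0.57 ± 0.23 (adjusted p = 0.794).

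In all, 9 of 7453 probe sets were called in the average over ages, 4 higher and 5 lower in mdx muscle. Of these, 6 had 1 gene symbol each, and the other 3, with log2 fold changes of -1.40, -1.09 and 0.65, had several. The probe set with 0.65 lost its call in 5 of 36 alternatives. In 4 of these 1 array was left out (adjusted p between 0.0518 and 0.0638). At an unadjusted p under 0.05, 413 probe sets passed. The calls of Dmd, Myl4 and Erdr1 held in each alternative in which they were tested, including each array left out in turn, and the stricter filter removed Dmd. Ctss lost its call with the replicate block (adjusted p = 0.0968). Qrsl1 lost its call without any 1 of 19 arrays (adjusted p between 0.0534 and 0.128), and kept it only without control 14-day replicate 2, control 56-day replicate 3, or mdx 14-day replicate 2, 28-day replicate 2 or 56-day replicate 1. It also lost it with the replicate block (adjusted p = 0.1), without the filter (0.0741), with age and genotype as additive terms (0.0561), without the arrays that stood apart (0.103) and with the largest signal of each array as a covariate (0.112). Mt2 lost its call (adjusted p between 0.0509 and 0.064) without control 14-day replicate 2, 28-day replicate 1 or 3, 56-day replicate 1 or 112-day replicate 1, or without mdx 28-day replicate 3, 56-day replicate 2 or 112-day replicate 1. Its adjusted p was 0.0884 without the arrays that stood apart and 0.0565 with the largest signal of each array as a covariate.

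**Figure D1:**
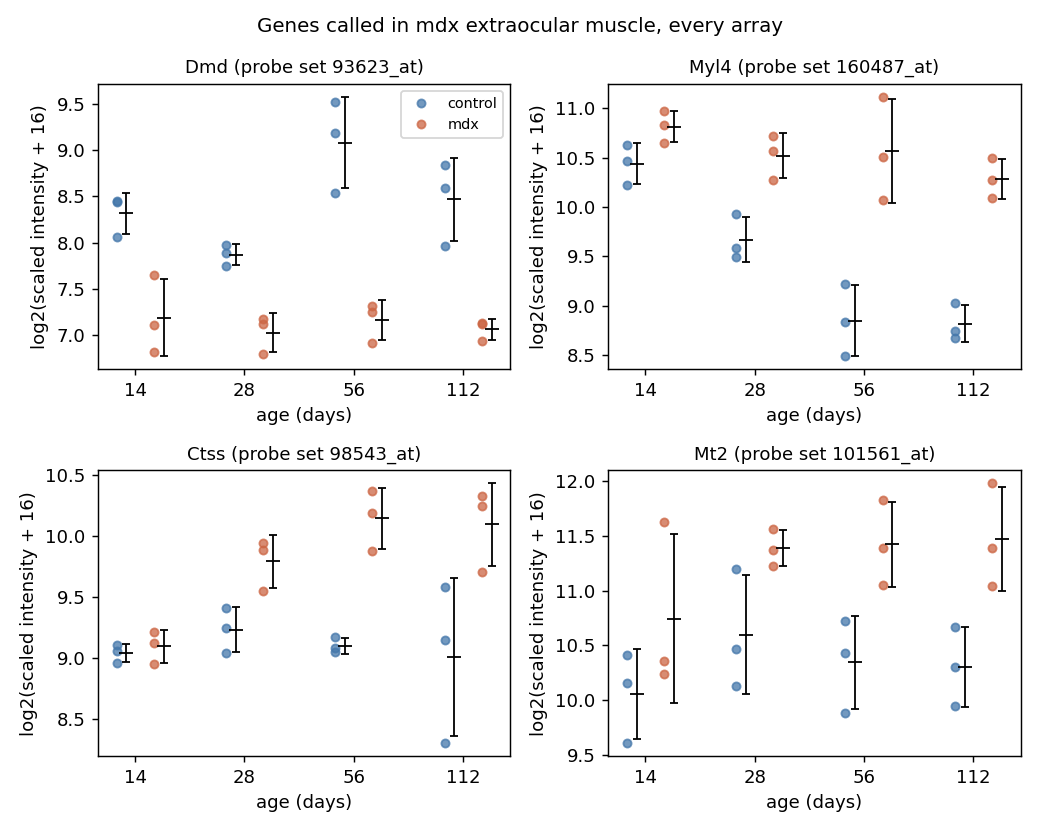
Level of Dmd, Myl4, Ctss and Mt2, as log2(scaled intensity + 16), on every array at 14, 28, 56 and 112 days, control in blue and mdx in orange, with the mean and SD of each group of 3 arrays in black. Dmd lies lower in mdx arrays at all 4 ages, and Myl4 lies higher at all 4.

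Utrn, the gene of the dystrophin relative utrophin, showed no difference past the threshold. Its 2 probe sets had log2 fold changes of -0.02 ± 0.25 (adjusted p = 0.995) and -0.48 ± 0.27 (adjusted p = 0.885) averaged over ages. Of the 14 measured genes of the dystrophin complex, 8 were higher and 6 lower in mdx muscle, and Dmd was the 1 member called, both over all probe sets and adjusted over the list alone. The list had a mean shift of -0.01 and a median shift of 0.11, opposite in sign (camera adjusted p = 0.754).

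4 gene lists lay higher in mdx muscle over the ages, each with both correlation settings of camera. Genes of antigen presentation and the interferon response had the largest mean shift among them, 0.37 on the log2 scale, with 27 of 28 members higher (adjusted p = 6.71e-14, and adjusted p = 0.0375 with an estimated correlation). Of these genes 0 were called over all probe sets by limma, where 413 probe sets of all kinds passed an unadjusted p under 0.05, and 11 were called adjusted over the list alone. Among them, the interferon-induced GTPase gene Iigp1 had a log2 fold change of 1.01 ± 0.24 (adjusted p = 0.0113 adjusted over the list alone), H2-Aa, which encodes a chain of a class II antigen-presenting molecule, had 0.94 ± 0.28, Gbp3 0.60 ± 0.18 and Ifi204 0.59 ± 0.17. A second Iigp1 probe set had 0.23 ± 0.19 (adjusted p = 0.92). The macrophage and monocyte list had a mean shift of 0.28, with 25 of 29 members higher (adjusted p = 3.71e-10, and adjusted p = 0.0375 with an estimated correlation). Ctss was called over all probe sets, and 4 members adjusted over the list alone, which were Ctss, the chemokine gene Ccl8 with a log2 fold change of 1.02 ± 0.24, the lysozyme gene Lyz2 with 0.62 ± 0.16 and the complement gene C1qc with 0.47 ± 0.13.

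The myogenic regeneration list had a mean shift of 0.21, with 19 of 24 members higher (adjusted p = 0.000192, and adjusted p = 0.0375 with an estimated correlation). Myl4 was called over all probe sets, and 3 members adjusted over the list alone: Myl4, the cardiac and embryonic troponin T gene Tnnt2 with a log2 fold change of 0.65 ± 0.14, and the cell cycle inhibitor gene Cdkn1a with 0.51 ± 0.16. A second Cdkn1a probe set had 0.28 ± 0.10 (adjusted p = 0.739). The embryonic and perinatal myosin heavy chain genes had 0.40 ± 0.47 (Myh3, adjusted p = 0.922) and 0.40 ± 0.25 (Myh8, adjusted p = 0.888). Without control 112-day replicate 1, where both were lowest, these were -0.13 ± 0.08 and 0.12 ± 0.07 (adjusted p = 0.988 for both), and the list had a mean shift of 0.14. The immediate early list had a mean shift of 0.16, with 21 of 28 members higher (adjusted p = 6.75e-05, and adjusted p = 0.0375 with an estimated correlation). Of its members 0 were called over all probe sets and 1 adjusted over the list alone, the transcription factor gene Cebpd with a log2 fold change of 0.49 ± 0.11; Zfp36 had 0.50 ± 0.15. In the exact permutation of genotype labels within ages, the adjusted p was 0.00845 for the interferon list, 0.00938 for the macrophage list, 0.017 for the immediate early list and 0.0186 for the myogenic list.

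**Figure D2:**
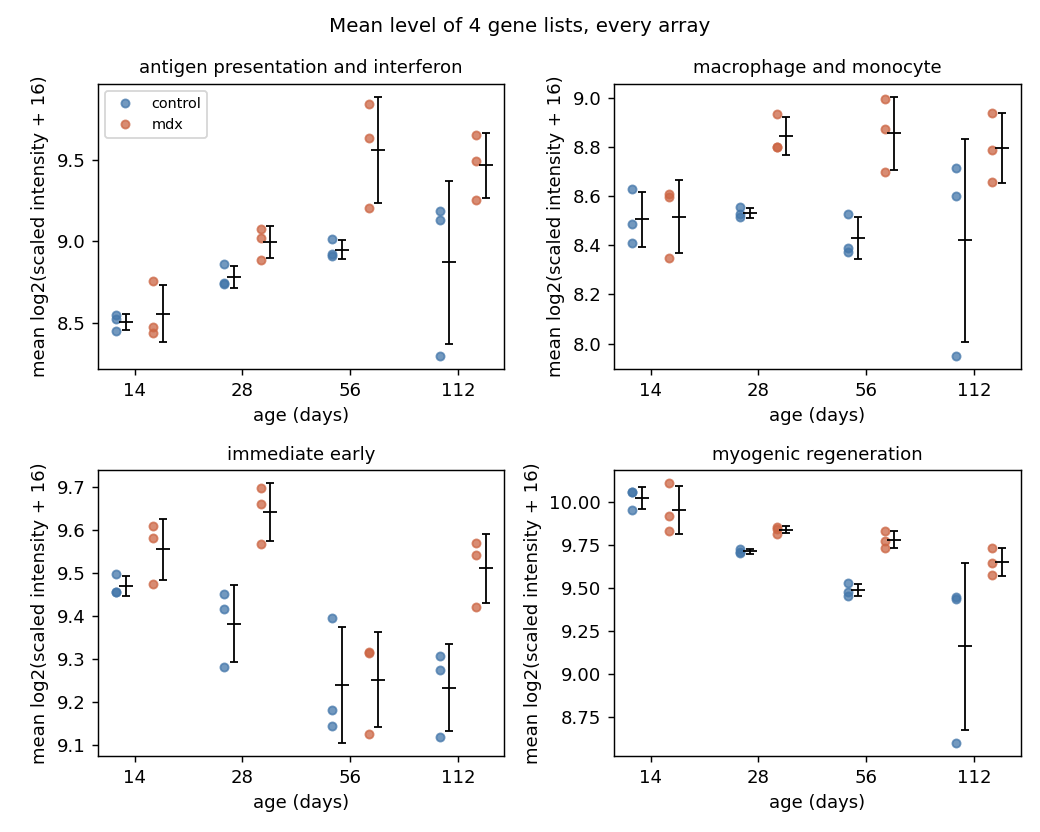
Mean level of the measured genes of 4 lists, as log2(scaled intensity + 16), on every array by age in days, control in blue and mdx in orange, with the mean and SD of each group of 3 arrays in black. Averaged over ages the mdx arrays lie higher by 0.37 for antigen presentation and interferon, 0.28 for macrophage and monocyte, 0.16 for immediate early and 0.21 for myogenic regeneration genes.

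Markers of the other cell types gave no call in this average with all arrays. The mean shift was 0.04 for lymphocytes, with 3 of 8 members higher, and 0.06 for mast cells and granulocytes. It was -0.04 for endothelium and vessel wall (-0.11 and called, adjusted p = 0.000647, without control 112-day replicate 1), -0.04 for nerve and myelin, 0.09 for adipocytes, 0.07 for erythroid genes and 0.06 for photoreceptor and retina genes. The lacrimal and Harderian gland list had 0.22, with 5 of 8 members higher (adjusted p = 0.374), and the surface epithelium and melanocyte list -0.01.

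Muscle and metabolic lists also stayed short of a call in the average with all arrays. The mean shift was 0.00 for fast and -0.02 for slow muscle isoforms, -0.03 for calcium handling, 0.10 for the neuromuscular junction, -0.05 for oxidative phosphorylation, -0.04 for the citric acid cycle and fatty acid oxidation and -0.01 for glycolysis and glycogen. The extracellular matrix and fibrosis list had 0.06 (27 of 45 members higher, adjusted p = 0.32), proliferation 0.03, proteasome and atrophy 0.05, and antioxidant and heat shock genes 0.07. In the last of these Mt2 was the 1 gene called over all probe sets, and 2 genes were called adjusted over the list alone. The number of lists called rose from 4 to 7 without control 112-day replicate 1, with citric acid cycle (-0.06), endothelium and proteasome (0.07) added, and to 7 without the arrays that stood apart, with oxidative phosphorylation (-0.08), citric acid cycle (-0.08) and endothelium added. It was 6 without control 14-day replicate 1 or control 56-day replicate 2, with oxidative phosphorylation and citric acid cycle added.

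At 14 days no gene with a symbol of its own was called. The 1 probe set called, lower in mdx muscle with a log2 fold change of -1.83 ± 0.30 (SE, adjusted p = 0.0348), had several symbols, and 373 probe sets passed an unadjusted p under 0.05. Zfp36, an immediate early gene that encodes an RNA-binding protein, had a log2 fold change of 1.35 ± 0.31 (adjusted p = 0.462). By camera, 7 lists were called at the preset correlation and 0 with an estimated correlation. The adipocyte list had a mean shift of 0.40 (11 of 12 members higher, adjusted p = 0.288 with an estimated correlation), the antioxidant list 0.14 and the proteasome list 0.13 (adjusted p = 0.629 and 0.99 with an estimated correlation). Lower in mdx muscle were the fast muscle list with -0.53 (16 of 19 members lower), oxidative phosphorylation with -0.19, proliferation with -0.24 and surface epithelium with -0.43 (adjusted p = 0.99, 0.99, 0.94 and 0.629 with an estimated correlation). In these 7 lists 0 members were called by limma over all probe sets or adjusted over the list alone. The count of 1 became 0 without any 1 of the control 14-day arrays or mdx replicate 3, 3 without mdx replicate 1 and 2 without mdx replicate 2. With the largest signal of each array as a covariate it was also 0, and the fast muscle and oxidative phosphorylation shifts became -0.02 and 0.03. With quantile normalization 5 of the 7 lists lost their call, all but adipocyte and proliferation.

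At 28 days Dmwd, a gene next to the myotonic dystrophy kinase gene, was the 1 probe set called. It fell to an intensity of 72.8 ± 11 in mdx muscle, against 413.6 ± 82.6 in control muscle (SD, n = 3 arrays each). The log2 fold change was -2.27 ± 0.24 (SE, adjusted p = 1.98e-05), a fold of 4.81. At an unadjusted p under 0.05, 226 probe sets passed. By camera, 5 lists were called: macrophage and monocyte with a mean shift of 0.31 (23 of 29 members higher), immediate early with 0.26 (22 of 28), oxidative phosphorylation with -0.23 (40 of 51 members lower), fast muscle isoforms with -0.35 (16 of 19 lower) and endothelium and vessel wall with -0.21. With an estimated correlation 0 were called (smallest adjusted p = 0.0782). Fos, an immediate early transcription factor gene, had a log2 fold change of 1.02 ± 0.34 (adjusted p = 1), and Ccl8 had 1.36 ± 0.48 (adjusted p = 1). With only the 28-day arrays in the fit, or with the stricter filter, 0 probe sets were called by limma (233 and 132 at an unadjusted p under 0.05), and without control replicate 1 the count was 2. With the largest signal of each array as a covariate the fast muscle and oxidative phosphorylation shifts became 0.27 and 0.03, and with quantile normalization -0.07 and -0.04.

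At 56 days Myl4, Plac8 and Uba7 rose and Dmd fell in mdx muscle. Myl4 had an intensity of 1571 ± 584 in mdx and 454.9 ± 118 in control muscle (SD, n = 3 arrays each), a log2 fold change of 1.72 ± 0.23 (SE, adjusted p = 0.00144). Plac8 rose by 1.55 ± 0.25 on the log2 scale (adjusted p = 0.00865), and Uba7, the activating enzyme for the interferon-induced modifier ISG15, by 1.17 ± 0.20 (adjusted p = 0.0179). The second Myl4 probe set had 0.30 ± 0.27 (adjusted p = 0.681). At an unadjusted p under 0.05, 911 probe sets passed. By camera, 5 lists were called at the preset correlation, all higher in mdx muscle, and 0 with an estimated correlation. Antigen presentation and interferon genes had a mean shift of 0.62 (adjusted p = 0.296 with an estimated correlation, 26 of 28 members higher, 9 called adjusted over the list alone and 0 over all), with the interferon-induced gene Ifit3 at 1.71 ± 0.44. The macrophage and monocyte list had 0.43 (adjusted p = 0.296 with an estimated correlation, 23 of 29 members higher, 5 called adjusted over the list alone and 0 over all), with Ctss at 1.05 ± 0.24 and Ccl8 at 1.79 ± 0.48. Myogenic regeneration had 0.29, fast muscle isoforms 0.86 and oxidative phosphorylation 0.33 (adjusted p = 0.296, 0.605 and 0.605 with an estimated correlation).

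The 56-day count of 4 rested on few arrays. It was 83 without control 56-day replicate 1, 7 without control replicate 3, and 2 without control replicate 2, mdx replicate 1 or mdx replicate 3. Uba7 lost its call without control replicate 2 or 3 or mdx replicate 1 or 3 (adjusted p between 0.0644 and 0.217), and Plac8 without control replicate 2 or mdx replicate 1 or 3 (adjusted p between 0.0644 and 0.139). With only the 6 arrays of this age in the fit, limma called 0 probe sets (689 at an unadjusted p under 0.05). With the largest signal of each array as a covariate the fast muscle shift was 0.28 and the oxidative phosphorylation shift 0.09, and without the arrays that stood apart 0.58 and 0.17, both without a call. With quantile normalization the oxidative phosphorylation shift was 0.08.

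At 112 days Myl4 was the 1 probe set called, with an intensity of 1244 ± 183 in mdx and 437.8 ± 60.4 in control muscle (SD, n = 3 arrays each). It rose by 1.47 ± 0.23 on the log2 scale (SE, adjusted p = 0.0151). The second Myl4 probe set had -0.01 ± 0.27 (adjusted p = 0.999). Myh3 had a log2 fold change of 2.23 ± 0.94 and Myh8 of 1.46 ± 0.50 (adjusted p = 0.862 for both), which rested on control replicate 1. Without it they were 0.08 ± 0.18 and 0.34 ± 0.15 (adjusted p = 1 for both). By camera, 5 lists were called at the preset correlation, all higher in mdx muscle, and 0 with an estimated correlation. Antigen presentation and interferon genes had a mean shift of 0.60 (adjusted p = 0.0987 with an estimated correlation, 26 of 28 members higher, 6 called adjusted over the list alone and 0 over all), among them the class II invariant chain gene Cd74 with 0.83 ± 0.28 and Gbp2 with 1.61 ± 0.55. Myogenic regeneration had 0.49 (3 called adjusted over the list alone, 1 over all), macrophage and monocyte 0.38, immediate early 0.28 and extracellular matrix 0.25 (adjusted p = 0.0951, 0.167, 0.0951 and 0.752 with an estimated correlation).

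At 112 days 419 probe sets passed an unadjusted p under 0.05. The count of 1 was 0 without control 112-day replicate 2 or mdx replicate 1 or 3, where Myl4 had adjusted p-values between 0.116 and 0.248. It was 3 without control replicate 1 and 2 without control replicate 3, and 0 with quantile normalization or with only the 6 arrays of this age (410 and 398 at an unadjusted p under 0.05). Without the arrays that stood apart the matrix shift was -0.04, and the interferon, myogenic and macrophage shifts were 0.31, 0.21 and 0.14.

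A change of the mdx effect with age was tested gene by gene, and Dmwd was the 1 probe set called for a genotype by age interaction (adjusted p = 0.00313). Its log2 fold change of -2.27 at 28 days stood against -0.28 at 14, 0.28 at 56 and -0.01 at 112 days, each ± 0.24 (SE). For Myl4 the log2 fold changes ran 0.38, 0.85, 1.72 and 1.47 from 14 to 112 days, and the interaction had an adjusted p of 0.649. For Dmd the interaction had an adjusted p of 0.781, so that the calls of Dmd and Myl4 at some ages and not at others were not shown to differ. At an unadjusted p under 0.05, 437 probe sets passed. With the replicate block, in keeping with the pairing assumed at 28 days, Dmwd had an adjusted p of 0.127 for the interaction. Limma then called 0 probe sets (612 at an unadjusted p under 0.05). With the stricter filter the count was also 0, since Dmwd was no longer tested, and it was 2 without mdx 14-day replicate 1, control 28-day replicate 1 or control 56-day replicate 1.

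Between 14 and 112 days control muscle lost RNA of extracellular matrix genes. Col3a1 fell from an intensity of 2909 ± 248 to 185.5 ± 76.1 (SD, n = 3 arrays each), a log2 fold change of -3.94 ± 0.29 (SE, adjusted p = 1.83e-08). Col5a2 had -2.86 ± 0.23, Postn, the gene of the matrix protein periostin, -3.26 ± 0.45, the elastin gene Eln -3.16 ± 0.62 and the basement membrane gene Nid2 -3.21 ± 0.51. At 112 days the mean control intensities of Eln and Nid2, 29.25 and 79.96, lay under the filter intensity of 125.7. Of the 45 measured extracellular matrix and fibrosis genes, 24 fell and 0 rose over all probe sets, and 30 fell and 2 rose adjusted over the list alone. The mean shift of this list was -1.10 (adjusted p = 2.23e-18, and adjusted p = 0.0421 with an estimated correlation).

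Meg3, a maternally expressed noncoding RNA, fell from 3847 ± 208 to 104.1 ± 21.6, a log2 fold change of -5.02 ± 0.45 (adjusted p = 2.35e-07), and the paternally expressed gene Mest had -2.99 ± 0.33. Of the myogenic regeneration genes, 11 of 24 fell over all probe sets and 13 adjusted over the list alone, with 1 higher in the latter. The mean shift was -0.86 (adjusted p = 2.22e-06, and adjusted p = 0.0276 with an estimated correlation). Among them Dlk1 had a log2 fold change of -2.03 ± 0.23, Mdk -1.77 ± 0.42, Myl4 -1.62 ± 0.23 and the cyclin gene Ccnd1 -0.92 ± 0.21. The second probe set had -0.47 ± 0.27 (adjusted p = 0.289) for Myl4 and -1.14 ± 0.60 (adjusted p = 0.237) for Ccnd1. Other named falls were Clcn5 with -3.29 ± 0.37, Fabp7 with -2.87 ± 0.53 and Atp2a1, the calcium pump of fast muscle, with -3.87 ± 1.12 (adjusted p = 0.0287). At 112 days the mean control intensities of Clcn5, Fabp7 and Meg3, 24.55, 50.48 and 104.1, lay under the filter intensity of 125.7. The Atp2a1 call was lost without control 14-day replicate 2 or 3 or 112-day replicate 1 or 3 (adjusted p between 0.0768 and 0.112), and with the largest signal of each array as a covariate its log2 fold change was -2.30.

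The glutathione transferase gene Mgst1 rose from 394.4 ± 98.2 to 1890 ± 213, a log2 fold change of 2.24 ± 0.19 (adjusted p = 9.32e-08) over the same span, and the cytochrome gene Cyp2e1 by 2.01 ± 0.24. Tspan8 rose by 4.10 ± 0.60, the carboxylesterase gene Ces1d by 3.38 ± 0.60 and the amylase gene Amy1 by 2.23 ± 0.32. H2-Aa rose by 3.15 ± 0.55 and the class I gene H2-K1 by 2.40 ± 0.41. Phka1, a subunit of phosphorylase kinase, rose by 2.41 ± 0.46, Sac3d1 by 3.09 ± 0.47 and the stress gene Gadd45b by 2.26 ± 0.58. Gadd45b lost its call without control 14-day replicate 2 or 3 (adjusted p of 0.0846 and 0.0562). At 14 days the mean control intensity was 13.5 for Tspan8, 30.7 for Ces1d, 62.4 for H2-Aa, 63.5 for Gadd45b and 76.4 for Amy1. It was 93.2 for Sac3d1 and 120.5 for H2-K1. Each of these lay under the filter intensity of 125.7. Without detection calls it cannot be said whether these RNAs were present at 14 days. The 20 named genes had 9 further tested probe sets. Of these 8 had the same sign and 6 were called, while the further probe set of Sac3d1 had 0.14 (adjusted p = 0.881), that of Clcn5 -0.41 (adjusted p = 0.62) and 1 of the 2 of H2-K1 -0.43 (adjusted p = 0.508).

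In all, 813 probe sets were called between 14 and 112 days in control muscle, 387 higher and 426 lower, and 1906 passed an unadjusted p under 0.05. By camera, 12 lists were called, and extracellular matrix and myogenic regeneration held with an estimated correlation. The other 10 had adjusted p-values of 0.0612 or more with an estimated correlation. They were higher for antioxidant and heat shock genes (mean shift 0.34), antigen presentation and interferon (0.37), glycolysis and glycogen (0.33) and proteasome and atrophy (0.30), and lower for nerve and myelin (-0.68), mast cells and granulocytes (-0.58), endothelium and vessel wall (-0.56), the neuromuscular junction (-0.56), proliferation (-0.47) and immediate early genes (-0.24). Without the arrays that stood apart 8 of the 12 stayed called, and the mast cell, immediate early, neuromuscular junction and endothelium lists had -0.43, -0.18, -0.25 and -0.28. The interferon list then had 0.66. The count of 813 was 465 without control 14-day replicate 1, 533 without control 14-day replicate 3, 512 without control 112-day replicate 1 and 380 with only the control arrays in the fit.

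**Figure D3:**
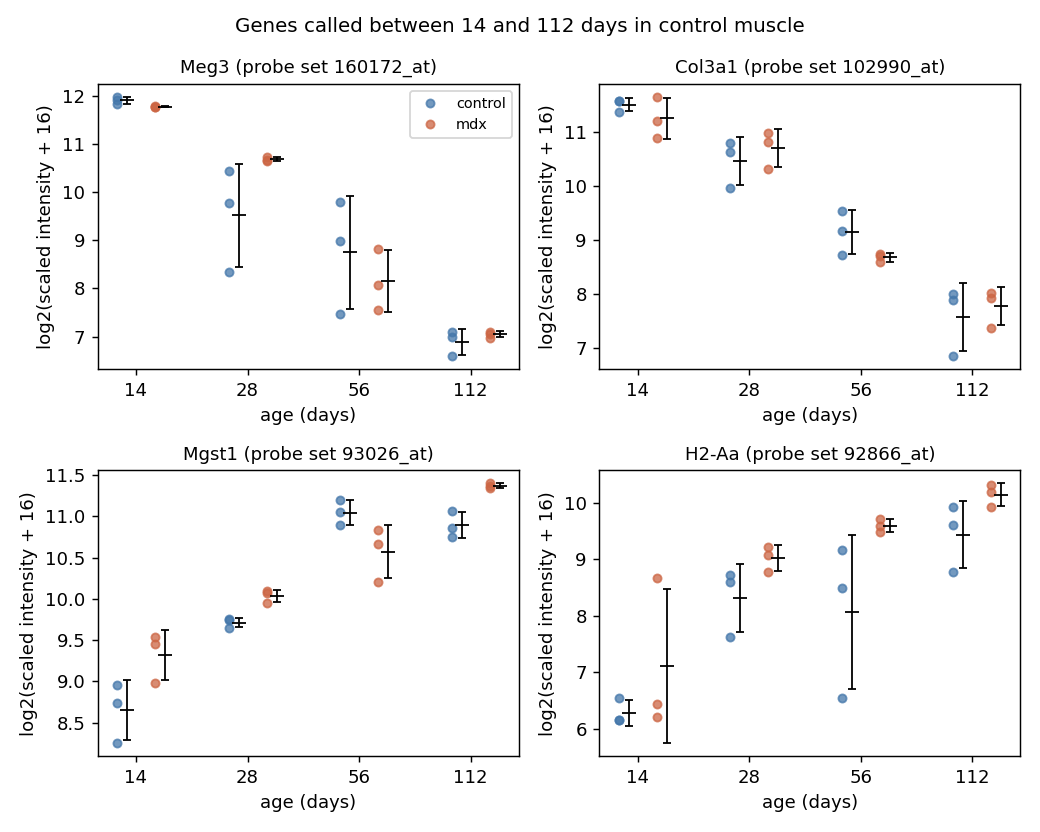
Level of Meg3, Col3a1, Mgst1 and H2-Aa, as log2(scaled intensity + 16), on every array by age in days, control in blue and mdx in orange, with the mean and SD of each group of 3 arrays in black. Between 14 and 112 days control muscle has log2 fold changes of -5.02 for Meg3, -3.94 for Col3a1, 2.24 for Mgst1 and 3.15 for H2-Aa.

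Across the 4 ages of control muscle, Meg3 had intensities of 3847 ± 208, 853.3 ± 537, 508.5 ± 356 and 104.1 ± 21.6 (SD, n = 3 arrays each) at 14, 28, 56 and 112 days. Col3a1 had 2909 ± 248, 1437 ± 401, 563.2 ± 159 and 185.5 ± 76.1, and Mgst1 394.4 ± 98.2, 824.0 ± 34.2, 2111 ± 226 and 1890 ± 213. Across the 4 control ages 1146 probe sets were called, and 2560 passed an unadjusted p under 0.05. By step, 21 were called from 14 to 28 days (12 higher, 9 lower), 498 from 28 to 56 days (242 higher, 256 lower) and 57 from 56 to 112 days (33 higher, 24 lower). The count across ages was 702 without control 14-day replicate 1, 712 without control 14-day replicate 3, 329 with only the control arrays and 351 with the largest signal of each array as a covariate.

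The counts of the steps moved with single arrays. From 14 to 28 days 21 became 2, 8 or 5 without control 14-day replicate 1, 2 or 3, and 5, 3 or 3 without control 28-day replicate 1, 2 or 3. From 28 to 56 days 498 became 24 or 292 without control 28-day replicate 2 or 3, and 193 or 132 without control 56-day replicate 2 or 3. With the largest signal of each array as a covariate, 0 probe sets were called by limma from 28 to 56 days (794 at an unadjusted p under 0.05), and with only the control arrays 8 were called. From 56 to 112 days 57 became 148 without control 56-day replicate 1, and 7, 24 or 171 without control 112-day replicate 1, 2 or 3.

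Between 14 and 112 days, all 20 genes named for control muscle had the same sign in mdx muscle, and 15 were called there. Col3a1 fell by 3.49 on the log2 scale (± 0.29 SE, adjusted p = 1.93e-07), Meg3 by 4.74 ± 0.45 and Col5a2 by 2.46 ± 0.23. H2-Aa rose by 3.04 ± 0.55, Cyp2e1 by 2.11 ± 0.24 and Mgst1 by 2.05 ± 0.19. Not called in mdx muscle were Ces1d with a log2 fold change of 1.18 ± 0.60 (adjusted p = 0.363), Sac3d1 with 1.28 ± 0.47, Phka1 with 1.30 ± 0.46, Atp2a1 with -1.97 ± 1.12 and Fabp7 with -0.63 ± 0.53 (adjusted p = 0.675).

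In mdx muscle 295 probe sets were called between 14 and 112 days, 129 higher and 166 lower, and 1116 passed an unadjusted p under 0.05. Of these 219 were also called in control muscle, 89 higher in both, 130 lower in both and 0 in opposite directions, where independent lists would share 6.70 and 9.49. The comparisons of the 2 genotypes share no array, but they share the estimate of the spread of each probe set. Their calls can therefore coincide more often than those of independent lists. Across the 7453 probe sets, which are not independent replicates, the log2 fold changes correlated with r = 0.651 and rho = 0.564. By camera, 11 lists were called in mdx muscle and 0 with an estimated correlation. Extracellular matrix genes had a mean shift of -0.83, with 18 of 45 lower and 1 higher over all probe sets and 25 and 2 adjusted over the list alone (adjusted p = 0.0584 with an estimated correlation). Antigen presentation and interferon genes had 0.91, with 7 of 28 called over all probe sets and 13 adjusted over the list alone (adjusted p = 0.0716 with an estimated correlation). The other 9 had adjusted p-values of 0.0716 or more with an estimated correlation. Lists with a higher mean were antioxidant and heat shock (0.32), macrophage and monocyte (0.28), glycolysis and glycogen (0.22) and lacrimal and Harderian gland (0.78). Lower were myogenic regeneration (-0.30), endothelium and vessel wall (-0.37), the neuromuscular junction (-0.32), the dystrophin complex (-0.26) and erythroid genes (-0.41, adjusted p = 0.0924 with quantile normalization). The count of 295 was 125, 151 or 146 without mdx 112-day replicate 1, 2 or 3, and 177 or 174 without mdx 14-day replicate 1 or 2. It was 502 without the arrays that stood apart, which are controls that enter the shared estimate of the spread.

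**Figure D4:**
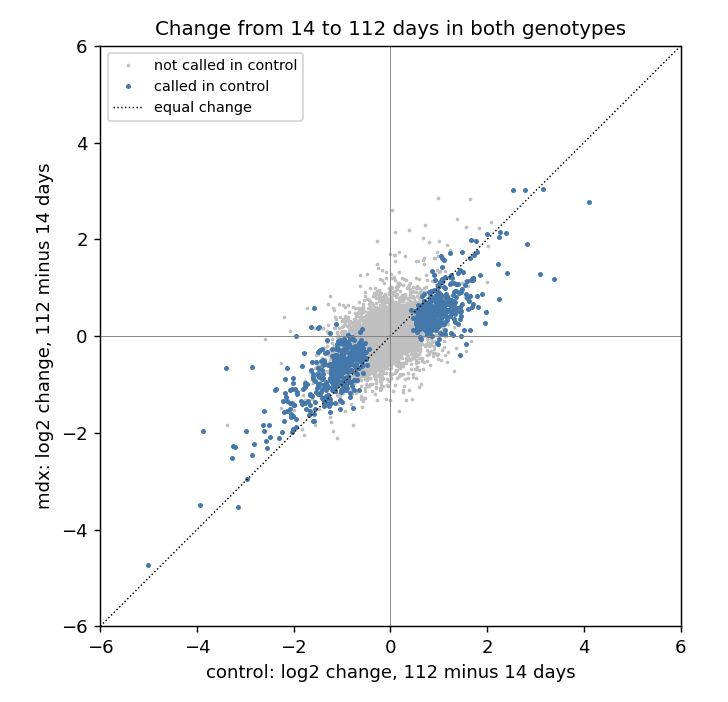
Log2 fold change between 14 and 112 days in control muscle (horizontal axis) and mdx muscle (vertical axis) for each of 7453 probe sets, with those called in control muscle in blue, the rest in grey, and a dotted line of equal change. Of the 813 called in control muscle, 795 have the same sign in mdx muscle.

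The difference of the 112 against 14 day change between the genotypes was tested for each probe set, and limma called 0, with 284 at an unadjusted p under 0.05. Among the 20 genes named for control ageing, the widest gaps were those of Fabp7, with a difference of 2.24 on the log2 scale (mdx minus control), and Ces1d, with -2.19 (adjusted p = 0.969 for both). Myh3 had a difference of 2.59 ± 1.32 (SE) and Myh8 of 1.44 ± 0.71 (adjusted p = 0.969 for both), which rested on control 112-day replicate 1. Without it they were 0.45 ± 0.24 and 0.32 ± 0.21 (adjusted p = 0.998 for both). By camera, 8 lists were called and 0 with an estimated correlation (smallest adjusted p = 0.194). Antigen presentation and interferon genes had a mean difference of 0.55, with 24 of 28 members higher, and myogenic regeneration genes 0.56, with 21 of 24 members higher. Without the arrays that stood apart these were 0.26 and 0.28, and 4 of the 8 lists stayed called.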

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

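Tests of a signal ceiling as the source of the low myosin signal, of lymphocytes and of less muscle as sources of the interferon shift were chosen after those results had been seen; the fits without the arrays that stood apart and with the largest signal as a covariate were also added after the data had been seen.

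The mdx effect on Dmwd differed between ages, with an adjusted p of 0.00313 for the interaction. With the replicate block the adjusted p was 0.127. In 21 of 100 drawn splits of the arrays within ages at least 1 probe set was called for an interaction, the real count being 1 and the highest other 2, so that chance cannot be excluded.

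The change from 14 to 112 days differed between genotypes for 8 gene lists by camera, and for 0 of them with an estimated correlation (adjusted p from 0.194 for myogenic regeneration to 0.633 for the matrix and proteasome lists). The mean difference, mdx minus control, was 0.563 for myogenic regeneration (adjusted p = 0.000772), 0.366 for macrophage and monocyte, 0.545 for antigen presentation and interferon, 0.277 for extracellular matrix and fibrosis, 0.359 for nerve and myelin and 0.636 for surface epithelium and melanocyte genes. It was -0.165 for proteasome and atrophy and -0.389 for adipocyte genes. Without the arrays that stood apart 4 of the 8 stayed called: myogenic regeneration (0.281), interferon (0.256), adipocyte (-0.533) and surface epithelium (0.537). The macrophage, nerve, proteasome and matrix differences were then 0.13, 0.147, -0.115 and -0.00656. Among single probe sets limma called 0 for this difference, with 284 at an unadjusted p under 0.05, and since the real count is 0, all 100 splits reach it whatever the data (highest other 1), which says nothing about chance.

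The counts were set against other splits of the arrays. At a single age the 10 splits are too few for a share under 0.05. The real count was 1 at 14 days and the highest other 1, with 2 splits reaching 1. At 56 days it was 4 against 2, with 1 split, the real one, reaching 4, and at 112 days 1 against 1, with 2 splits reaching it. At 28 days the real count was 1 and the highest other 3, with 2 splits reaching 1. There the split that called 3 keeps some of the assumed pairs together, and the other splits that part all 3 pairs called 0. As the pairing was not tested, this does not set that split aside. For the average over ages 1 of 100 splits, the real one, reached 9, the highest other being 1, so that chance is unlikely for free splits. That holds for the count of 9 and not for each probe set in it. These splits, those for the interaction and the exact permutation of the list means took no account of the pairing assumed at 28 days.

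For control muscle 1 of 100 splits of the ages, the real one, reached the 1146 probe sets called across ages (highest other 525). The same was true of the 813 called between 14 and 112 days (highest other 321). In mdx muscle 1 of 100 reached 295 (highest other 81). Chance is unlikely as the source of these 3 counts. For the step from 28 to 56 days 3 of 100 splits, the real one included, reached 498. For the step from 56 to 112 days 4 of 100, the real one included, reached 57. These shares lie under 0.05, but the highest others, 750 and 382, exceed the real counts. Chance can therefore not be excluded for either step. For the step from 14 to 28 days 8 of 100 splits reached 21, and chance cannot be excluded. The highest other there was 508. For this step and that from 56 to 112 days, splits that call several times the real count point to a structure of the samples, which age itself may be, as the splits regroup the arrays of all 4 ages.

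Control 112-day replicate 1 had the lowest embryonic and perinatal myosin signals of all arrays. Its Myh8 intensity was 131.9, against at least 1352 on the other 23 arrays. That level lies near the filter intensity of 125.7. Without detection calls it cannot be said whether Myh8 RNA was present on this array. Its Myh3 level was 5.84 on the log2 scale, against a median of 12.3 and at least 11.8 on the other 23 arrays. A ceiling of a bright scan is excluded, since all 15 arrays with a lower largest signal kept Myh3 within 1 log2 unit of the median. Muscle from another body region or a mixed-up sample may be the source. Its 12 Hox probe sets had a mean of 8.82, against 7.35 to 8.60 on the other arrays (SD 0.305), a gap to the highest of them that is under 1 SD, so that this stays open and cannot be told apart from a difference between animals.

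The brightest probe sets lost signal on some arrays, among them the 56-day controls, where Acta1, the skeletal actin gene, had an intensity of 1151 ± 1310 against 16250 ± 9250 at 28 days (SD, n = 3 arrays each). A ceiling of a bright scan may be the source, since 17 bright ribosomal protein probe sets moved with 24 bright muscle probe sets in deviations from group means (r = 0.859, permutation p = 0.00037, adjusted p = 0.00037; rho = 0.852, permutation p = 0.00035; r = 0.865 without the 2 farthest of 24 arrays). Less muscle in the dissected tissue may be the source as well, since 21 dimmer muscle probe sets moved with the bright ones too (r = 0.858, permutation p = 1e-05, the smallest the resamples can give, adjusted p = 2e-05; rho = 0.881; r = 0.854 without the 2 farthest). These were the 2 relations computed, and they do not separate the sources. Dim probe sets outside muscle were not compared, and ribosomal protein genes are not particular to muscle. The relation of the dimmer muscle probe sets is therefore no specific sign of less muscle. Age stays open as a biological source, as untested.

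Antigen presentation and interferon genes were higher in mdx muscle averaged over ages, by 0.369 ± 0.0969 (SE of the list mean). The signal ceiling as the whole source is excluded, since the shift with the largest signal as a covariate was 0.357 ± 0.102, or 96.6% of it. Less muscle in the mdx tissue, with vessel wall, nerve and fat in its place, does not account for the whole shift. The shift exceeded that of vessel wall, nerve and adipocyte genes by 0.366 ± 0.082. This comparison was chosen after the results had been seen. The lacrimal and Harderian gland list, higher by 0.22, was left out of it, so gland tissue is not excluded. Lymphocytes may contribute: the shift exceeded theirs by 0.325 ± 0.195, which does not decide, as 8 lymphocyte genes were measured. The macrophage and monocyte list was also higher, by 0.282, and these cells were not tested as a source of the interferon shift. The mdx genotype is likewise an open biological source and a hypothesis.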

How the results depend on the processing

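The fits without the arrays that stood apart and with the largest signal of each array as a covariate were chosen after the data had been seen, as were all alternatives for the steps between ages and for the difference between genotypes. Over all alternatives, 87 of 280 counts moved by more than 1.5 times, 77 of 882 named gene values lost their call and 3 gained one, and of 438 list values 79 lost their call and 6 turned the direction of the camera test. The causes were not tested.

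Array weights raised every count of probe sets but that of the difference between genotypes: to 3, 3, 174 and 7 at 14, 28, 56 and 112 days (1, 1, 4 and 1 in the fit described), to 14 for the average over ages (9), to 11 for the interaction (1), to 2425 across control ages (1146), to 1226 and 1312 between 14 and 112 days in control (813) and mdx muscle (295), and to 122, 1323 and 422 for the steps from 14 to 28 (21), 28 to 56 (498) and 56 to 112 days (57). The weights were estimated with a warning that the tolerance for convergence was not reached.

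With the replicate block, the count was 0 at 14 days, 12 at 56 days, 2 at 112 days and 0 for the interaction, and the step from 14 to 28 days gave 5. At 28 days, where the numbers were taken to pair, the count with the block was 1. The average over ages gave 6, control ages 918, 112 against 14 days 729 in control and 239 in mdx muscle, the step from 28 to 56 days 340, that from 56 to 112 days 45, and the difference between genotypes 0 (369 at an unadjusted p under 0.05 in limma). In the pairing check the correlations of the same number were 0.253, -0.0233 and 0.0433 at 14 days, -0.0192, 0.00964 and 0.185 at 56 days and 0.0667, 0.0904 and 0.107 at 112 days. Between ages they were -0.193, -0.209 and -0.0426 in control and -0.189, -0.0693 and -0.18 in mdx muscle.

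At 14 days the larger offset gave 2, no variance trend 0, only the arrays of that age 0, leaving out the arrays that stood apart 2 and the largest signal as a covariate 0. At an unadjusted p under 0.05 limma passed 373, 268 and 264 probe sets in the 3 fits with 0, and 467 with the block. With only the arrays of that age, 28, 56 and 112 days each gave 0. The stricter filter gave 0 at 28 days and quantile normalization 0 at 112 days, where leaving out the arrays that stood apart gave 3. For the interaction no filter gave 2 and the stricter filter 0.

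With only the control arrays, the control ages gave 329, 112 against 14 days 380, and the steps 2, 8 and 4. With the largest signal as a covariate the control ages gave 351, the step from 28 to 56 days 0 and that from 56 to 112 days 20. Without the arrays that stood apart, 112 against 14 days in mdx muscle gave 502, the step from 14 to 28 days 72 and that from 56 to 112 days 6. No variance trend gave 10 for the step from 14 to 28 days, and the stricter filter 34 for that from 56 to 112 days.

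Leaving out 1 array at a time, the count ran from 0 to 3 at 14 days, 1 to 2 at 28 days, 2 to 83 at 56 days and 0 to 3 at 112 days. It ran from 6 to 11 for the average over ages and from 1 to 2 for the interaction. It ran from 702 to 1283 across control ages, from 465 to 833 between 14 and 112 days in control muscle and from 125 to 307 in mdx muscle. For the steps it ran from 2 to 8, from 24 to 700 and from 7 to 171.

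With the largest signal as a covariate the mean shift of fast muscle isoforms was -0.0185 at 14 days and 0.271 at 28 days, and that of oxidative phosphorylation 0.0281 and 0.0303. Without the arrays that stood apart the matrix list had -0.0383 at 112 days and -0.00656 for the difference between genotypes. The lists of antigen presentation and interferon, macrophage and monocyte, immediate early and myogenic regeneration genes kept their calls for the average over ages in all 30 alternatives.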

Other observations

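The lists and genes of this part were fixed before the data were seen, and the members described here were picked after. Among the markers of surface epithelium, 3 of 12 rose and 0 fell in mdx muscle between 14 and 112 days. The corneal crystallin gene Aldh3a1 rose by a log2 fold change of 2.03 ± 0.45 (SE, n = 3 arrays per group, adjusted p = 0.0107), the desmosome gene Dsp by 2.19 ± 0.60 (adjusted p = 0.0413) and the keratin gene Krt6a by 1.74 ± 0.47 (adjusted p = 0.0376). A second Krt6a probe set had 2.30 ± 0.77 (adjusted p = 0.112). In control muscle Aldh3a1 had 0.66 ± 0.45 (adjusted p = 0.382), Dsp 0.39 ± 0.60 (adjusted p = 0.747) and Krt6a 0.19 ± 0.47 (adjusted p = 0.853), and the change was not shown to differ between genotypes for these 3 genes (adjusted p = 0.969 for each). In control muscle the melanocyte gene Dct fell by 0.97 ± 0.30 (adjusted p = 0.0392). The surface epithelium and melanocyte list as a whole was not called in mdx (mean shift 0.515, adjusted p = 0.0934) or control muscle (-0.121, adjusted p = 0.739). For the difference of this change between genotypes it was called, with 0.636 (adjusted p = 0.0208, and adjusted p = 0.489 with an estimated correlation). At 14 days, where the change starts, the list was lower in mdx than in control muscle, with -0.428 (adjusted p = 0.0239, and adjusted p = 0.629 with an estimated correlation).

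Amy1, an amylase gene active in glands, rose in both genotypes, by 2.23 ± 0.32 in control and 1.48 ± 0.32 in mdx muscle (adjusted p = 8.65e-05 and 0.00864). Its mean intensity at 14 days, 76.4 in control and 120.9 in mdx muscle, lay under the filter intensity of 125.7. The salivary and lacrimal protein gene Bpifa2 had 1.83 ± 0.67 (adjusted p = 0.0788) and 2.24 ± 0.67 (adjusted p = 0.0623). The lacrimal and Harderian gland list had a mean shift of 0.563 in control (adjusted p = 0.129) and 0.779 in mdx muscle (adjusted p = 0.0279, and adjusted p = 0.0885 with an estimated correlation).

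Of the sex-linked genes, Eif2s3y, on the Y chromosome, had intensities between 245 and 706 over the 24 arrays and Uty, also on the Y chromosome, between 97.8 and 256. Other genes of the Y chromosome did not pass the filter: Kdm5d had 9.79 to 458, and the 2 probe sets of Sry had 1.63 to 54.6 and 19.6 to 219. Xist, made by the inactive X chromosome of females, had 8.06 to 73.6 and did not pass it either. The sex of the samples is not given in the sources used here.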
